A study of Homo sapiens with 12 samples.

How the data were processed

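RNA from LNCaP cells was measured by RNA sequencing in 12 libraries, 3 each from a vector control, USP22 overexpression, an shRNA control and an shRNA against USP22. Libraries were prepared with a stranded total RNA kit, per the labels' protocols, so transcripts without a poly(A) tail are included.

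The authors deposited a single table of raw read counts for 63677 Ensembl gene IDs, with no summary rows. STAR 2.5.2a, featureCounts 1.5.0-p3, DESeq2 1.14.1 and the hg19 build are named in the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of multiply mapped reads are not given in the sources used here, so reads of paralogs, histone copies, overlapping and antisense genes may be split or lost. No coordinates are given, because the annotation at hand is of another build.

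Groups and replicate numbers come from the sample labels, and each column of the table was matched to its sample by name. Overexpression columns carry a shorter form of the sample title. Gene symbols were found by ID for 39699 IDs, 62.3% of the table and 80.1% of tested genes, and IDs without a symbol held 7.71% of the reads. List members were matched by current or older symbols (894 of 929 entries). Gene types, GC content and length came from GENCODE 29, by ID, and were available for 95.4% of tested genes.

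Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr by group, which left 26076, and library sizes were scaled by TMM. A model of all 4 groups with 8 residual degrees of freedom was fitted with glmQLFit, and contrasts were tested with glmQLFTest: overexpression minus vector control, depletion minus shRNA control, their joint effect, their difference, and shRNA control minus vector control. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with a threshold of 0.05. Fold changes and standard errors are on the log2 scale, the latter from the fold change and its F statistic. CPM values use the TMM-scaled library sizes.

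In all, 36 gene lists were fixed before the data were examined. They covered prostate lineage genes, cell cycle, DNA repair, stress, metabolism, signalling, SAGA subunits and markers of other cells. Each was tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. On overexpression 10 lists were called with the preset and 1 with the estimated correlation, and on depletion 20 and 7. A call lost with the estimate does not by itself show a high correlation. For markers of other epithelial lines on depletion the call was lost although the estimate, 0.005, was below the preset. Some genes stand in more than 1 list. Some genes and lists count in the totals but are not reported here. The other lists not named in the report were not called on either comparison.

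Genes named in the text were chosen by a rule set at the same time. It took 14 preset genes, of which USP27X was not tested here, the 6 largest rises and falls of each comparison among called genes with a mean CPM of at least 5, replicates that do not overlap and a gene symbol that is not a clone name, up to 3 members of each of up to 6 lists with the smallest camera p, and 5 genes per direction of opposite and 3 of same change. Replicates did not overlap for 22.4% of genes on overexpression and 41.8% on depletion, where chance gives 10%.

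The depth of 77607469 to 103690001 reads per library sets the counting error. The procedure was tested on simulated data for all 26076 genes with 200 changed genes, 50 per fold size, in 5 simulations per comparison. For overexpression it recovered 12.8% of 1.25-fold, 41.2% of 1.5-fold, 59.6% of 2-fold and 86.4% of 4-fold changes, with 5.68% false calls. For depletion it recovered 11.6%, 42.8%, 65.2% and 88% of the same fold sizes, with 7.73% false calls, above the nominal share. The simulations changed fewer genes than were called in the data (1072 on overexpression and 5172 on depletion), so recovery there may differ. The number of simulations was raised to 5 after a single simulation per comparison had been seen. Replicate pairs differed by more than counting noise (chi-square per degree of freedom of at least 7.2), so no library was counted as a repeat of another.

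Alternatives were RLE scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, only the libraries compared, a replicate block, leaving out the 20 most abundant genes, stricter thresholds and leaving out each replicate. Added after seeing the data were voom with sample quality weights, protein-coding genes alone, and the depletion comparison without vector control replicate 3.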

Results

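RNA was sequenced from LNCaP cells, an androgen-sensitive line of human prostate cancer, in which the level of USP22 was raised or lowered. USP22 is the ubiquitin protease of the deubiquitinase module of the SAGA transcriptional coactivator complex. The 12 libraries formed 4 groups of 3: cells with a vector control (pLPLUC), cells overexpressing USP22, cells with a control shRNA and cells with an shRNA against USP22. Both shRNA groups received doxycycline at 1 ug/mL every 48 hours for 5 days, and the cells grew in hormone-proficient medium. The libraries held between 77607469 and 103690001 counted reads. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Vector control replicate 3 stood apart from the other vector control libraries. Its log2 values had an SD of 0.59 around the mean of its group mates, against 0.46 for replicates 1 and 2, and mitochondrial genes took 0.691% of its reads, against 1.04% and 1.24%.

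USP22 (ENSG00000124422) followed the labels in every library. It stood at 512.5 ± 45.9 CPM in the vector control and 1466 ± 52.2 CPM after overexpression (SD, n = 3 each). This is a 2.86-fold rise, a log2 fold change of 1.52 (SE 0.06, edgeR adjusted p = 4.29e-10). The shRNA lowered it from 477.6 ± 3.65 CPM to 257.6 ± 7.38 CPM, 0.539 of the control level (log2 fold change -0.89, SE 0.06, edgeR adjusted p = 5.41e-08). The replicates did not overlap in either comparison, and an exact two-sided permutation test of 3 against 3 values cannot go below p = 0.1. The fold change of the depletion was smaller in size than that of the overexpression: their sum on the log2 scale was 0.63 (SE 0.09, edgeR adjusted p = 0.000117). The 2 control lines did not differ detectably in USP22, with a log2 difference of -0.10 (edgeR adjusted p = 0.203).

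**Figure D1:**
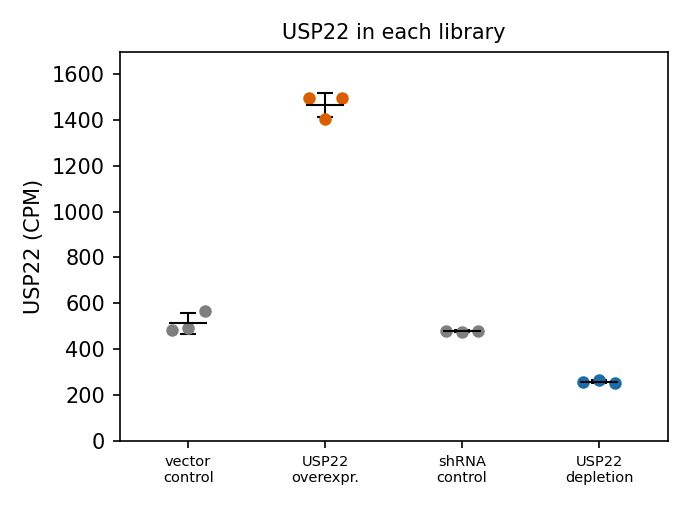
USP22 in CPM, reads scaled to the library size (linear axis from 0), in each of the 12 libraries. Points are libraries, horizontal marks are group means and error bars are 1 SD (n = 3). Overexpression libraries lie between 1406 and 1498 CPM and depletion libraries between 250.6 and 265.3 CPM, with both controls between 473.4 and 565.2 CPM.

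The first comparison asked which transcripts changed when USP22 was raised. Among the genes that rose was KCNJ3, an inwardly rectifying potassium channel, which went from 12.27 ± 1.47 to 60.12 ± 4.35 CPM (4.89-fold, edgeR adjusted p = 4.29e-10). UNC13C, a protein of synaptic vesicle priming, rose 3.64-fold, RALYL, an RNA-binding protein, 3.57-fold, and SLC22A3, an organic cation transporter, 2.72-fold. Among genes with a symbol and a mean of at least 5 CPM, the largest falls were in CLU, the secreted chaperone clusterin (from 28.79 ± 2.58 to 5.214 ± 0.463 CPM, edgeR adjusted p = 1.49e-10), DAPK1, a death-associated protein kinase (0.239 of the control level), and THBS1, a matrix glycoprotein (from 117.8 ± 5.3 to 33.49 ± 0.678 CPM, edgeR adjusted p = 1.7e-10). H2AJ, a histone variant, fell to 0.293, TMEM45B to 0.301 and H4C16, a histone H4 gene, to 0.308 of the control level, and reads of histone genes can be split between near-identical copies. In all, 1072 of 26076 tested genes changed, 393 higher and 679 lower, with 206 changed at least 2-fold (edgeR, Benjamini-Hochberg adjusted p under 0.05). This count rested on single libraries: it was 1876 (784 higher, 1092 lower) without vector control replicate 3, with 1020 of the 1072 still called, and 547, 511 and 621 without overexpression replicate 1, 2 and 3. It was 327 with only the 6 libraries compared, 1781 by DESeq2 and 2062 with no filter on low counts.

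Genes of neuroendocrine prostate cancer, a list fixed beforehand, leaned downward on overexpression, and KLK3, which encodes prostate-specific antigen, fell from 1247 ± 144 to 874.2 ± 25.2 CPM (log2 fold change -0.51, edgeR adjusted p = 0.00128). Of 10 tested neuroendocrine genes 3 fell: DDC, the aromatic amino acid decarboxylase (log2 fold change -1.54), SYT4, a synaptotagmin (-0.88), and ENO2, the neuronal enolase (-0.60), with edgeR adjusted p of 2.74e-09, 1.28e-05 and 0.000219. Adjusted over the list alone 4 fell and 1 rose. This was the 1 list whose camera call on overexpression (adjusted p = 2.02e-06) held with an estimated correlation (adjusted p = 0.02). Its median was close to 0 at -0.06 against a mean of -0.29, and without vector control replicate 3 the median was 0.08 while the test still pointed down.

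Protein-coding genes of the mitochondrial genome were the list that rose on overexpression. Of 13 genes 5 rose and none fell (9 rose adjusted over the list alone), among them MT-ND4L (1.65-fold), MT-ND5 (1.4-fold) and MT-CYB (1.49-fold), with edgeR adjusted p of 0.00562, 0.0244 and 0.0275. The camera adjusted p was 5.21e-08, and adjusted p = 0.46 with an estimated correlation. The mitochondrial share of reads was lowest in vector control replicate 3, and without that library the median log2 rise of the list went from 0.46 to 0.285. The calls of MT-ND5 and MT-CYB ended with only the 6 libraries compared and without any 1 of the overexpression replicates. Reads of these genes can be shared with nuclear copies of mitochondrial DNA.

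Stress, growth and signalling lists shifted downward by small amounts. Another split of the 6 libraries compared gave as many called lists as the real one (10 each). In the integrated stress response list of ATF4 and CHOP targets, 6 of 27 genes fell and 1 rose (14 fell and 1 rose adjusted over the list alone), among them SLC3A2, a subunit of amino acid transporters (0.724 of control), CHAC1 (0.736) and CARS1, a transfer RNA synthetase (0.817; edgeR adjusted p = 0.0111, but 0.0564 and 0.0682 without overexpression replicate 1 and 2). With only the 6 libraries compared these 3 genes no longer passed (edgeR adjusted p = 0.0589, 0.087 and 0.131). Their camera adjusted p was 8.46e-06, and adjusted p = 0.46 with an estimated correlation. In the list of TGF beta targets 6 of 12 genes fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 7.73e-05, and adjusted p = 0.28 with an estimated correlation). Its named falls were ID1 (log2 fold change -0.95), ID2 (-0.54) and ID3 (-0.57), which are better known as targets of BMP signalling. The calls of ID2 and ID3 ended with only the 6 libraries compared (edgeR adjusted p = 0.0519 and 0.063). Of 53 MYC targets 2 fell, PES1 (-0.47) and PA2G4 (-0.24), also 2 adjusted over the list alone, with edgeR calls that ended without overexpression replicate 2 (PES1, adjusted p = 0.0546) or without any 1 overexpression replicate (PA2G4, adjusted p = 0.117 to 0.198), and for both with only the 6 libraries compared (adjusted p = 0.12 and 0.198). The MYC list had a median of -0.13 (camera adjusted p = 0.00147, and adjusted p = 0.83 with an estimated correlation). The immediate early genes (median -0.19, 1 of 20 fell, 5 adjusted over the list alone), the ribosomal proteins (-0.09, 0 of 76 called by edgeR, also 0 adjusted over the list alone, 16 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma voom), the E2F and replication genes (-0.07, 2 of 52 fell, 3 adjusted over the list alone) and the nuclear respiratory chain genes (-0.09, 1 of 50 rose, also 1 adjusted over the list alone) had camera adjusted p of 0.0015, 0.00384, 0.0213 and 0.0221. With an estimated correlation these became adjusted p = 0.41 for the immediate early genes and adjusted p = 0.83 for the other 3 lists. Without vector control replicate 3 the camera calls of the MYC, ribosomal, E2F and respiratory chain lists were lost (adjusted p = 0.0651, 0.116, 0.116 and 0.0651). Their medians were then -0.06, -0.05, -0.04 and -0.06. PES1 and PA2G4 had smaller falls in that fit (-0.30 and -0.18) and were still called (edgeR adjusted p = 0.000187 and 0.0282). The E2F call also ended without overexpression replicate 2 (adjusted p = 0.0535), and the respiratory chain call without vector control replicate 1 or overexpression replicate 2 (adjusted p = 0.0646 and 0.0577), and both with only the 6 libraries compared (adjusted p = 0.073 each). Under the strict filter the calls of the immediate early, ribosomal, E2F and respiratory chain lists were lost (camera adjusted p = 0.118, 0.118, 0.204 and 0.204), and the immediate early median was -0.09.

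The second comparison asked which transcripts changed when USP22 was depleted. Genes of the UDP-glucuronosyltransferase 2B family, which includes enzymes that conjugate androgens, were among the rises: UGT2B11 went from 22.82 ± 0.87 to 124.3 ± 4.62 CPM (5.45-fold, edgeR adjusted p = 3.87e-11), UGT2B10 rose 3.89-fold, UGT2B28 3.44-fold and UGT2B15 3.32-fold. These are close paralogs, so the split of reads between them is uncertain. FUCA2, a fucosidase, rose 3.05-fold. Among genes with a symbol and a mean of at least 5 CPM, the largest falls were in ACTA2, smooth muscle actin, which went from 33.78 ± 1.45 to 4.718 ± 0.487 CPM (edgeR adjusted p = 1.54e-10), the interferon-induced GTPases GBP2 (0.176 of control) and GBP1 (0.184), ZNF608 (0.185), MDGA1 (0.19) and AGR2, a protein disulfide isomerase family member (0.2). KLK3 fell from 1428 ± 35 to 326.3 ± 34 CPM (0.228 of control, edgeR adjusted p = 1.54e-10). Some of these genes already differed between the shRNA and vector controls, with log2 differences of -1.98 for UGT2B15, -1.07 for UGT2B10 and 3.52 for MDGA1. UGT2B15 had 150.7 to 185.4 CPM in the vector control and 138.3 to 151.3 CPM after depletion. FUCA2 was higher in the shRNA control (1.31), and GBP2, ZNF608 and UGT2B28 did not differ detectably (edgeR adjusted p = 0.535, 0.58 and 0.214). In all, 5172 genes changed, 2450 higher and 2722 lower, with 825 changed at least 2-fold (edgeR). The count was 8375 (4081 higher, 4294 lower) without vector control replicate 3, which enters this comparison only through the shared estimate of the spread, with all 5172 among them, and 8115 with only the 6 libraries compared. Which direction had more genes depended on the procedure: 2606 rose and 2571 fell under RLE scaling, 3106 and 2603 with no filter on low counts, 2689 and 2511 with the strict filter, 2901 and 2801 by DESeq2, and 2635 and 2379 with protein-coding genes alone. More genes rose as well without shRNA control replicate 1 (1814 and 1721), shRNA control replicate 2 (2216 and 1868) and depletion replicate 3 (2463 and 1963).

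Cell cycle genes moved together on depletion. Of 52 G2 and mitosis genes 50 rose and none fell (52 rose adjusted over the list alone), with a median log2 fold change of 0.61. The kinetochore protein gene CENPF rose 1.7-fold, the spindle checkpoint kinase gene BUB1 1.7-fold and the securin gene PTTG1 1.84-fold (edgeR adjusted p = 1.56e-07, 1.86e-07 and 4.65e-07). Of 52 E2F and replication genes 46 rose and none fell (49 rose adjusted over the list alone), including GINS4 of the replicative helicase (1.74-fold), the sliding clamp PCNA (1.6-fold) and the primase subunit PRIM1 (1.66-fold). E2F1 had a log2 fold change of 0.44 (SE 0.10, edgeR adjusted p = 0.00594). The camera adjusted p of the lists were 1.03e-48 and 1.68e-31, and adjusted p = 0.021 and adjusted p = 0.036 with an estimated correlation. Without vector control replicate 3 the estimated correlation gave adjusted p = 0.033 and 0.066, so the E2F call was lost. With the preset correlation, another split of the 6 libraries compared called 17 lists, against 20 for the real split. This limits the camera p of all lists described for depletion. Replication-dependent histone genes rose in 20 of 24 cases (22 adjusted over the list alone; H2BC18 2.12-fold, H3C13 2.23-fold, H1-2 1.61-fold, with reads shared between copies uncertain), with adjusted p = 0.19 with an estimated correlation. Of 53 MYC targets 37 rose (43 adjusted over the list alone; POLR1B 1.36-fold, HSPD1 1.33-fold, PAICS 1.29-fold), with adjusted p = 0.14 with an estimated correlation, and MYC itself rose 1.61-fold (edgeR adjusted p = 1.78e-06). CDKN1A, which encodes the cell cycle inhibitor p21, fell to 0.563 of control (log2 fold change -0.83, edgeR adjusted p = 2.76e-06). CCND1 had a log2 fold change of -0.04 (edgeR adjusted p = 0.696). These shifts have to be read with the level of the control: the G2 and mitosis list lay 0.96 log2 units below the vector control in the shRNA control and 0.39 below it after depletion.

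**Figure D2:**
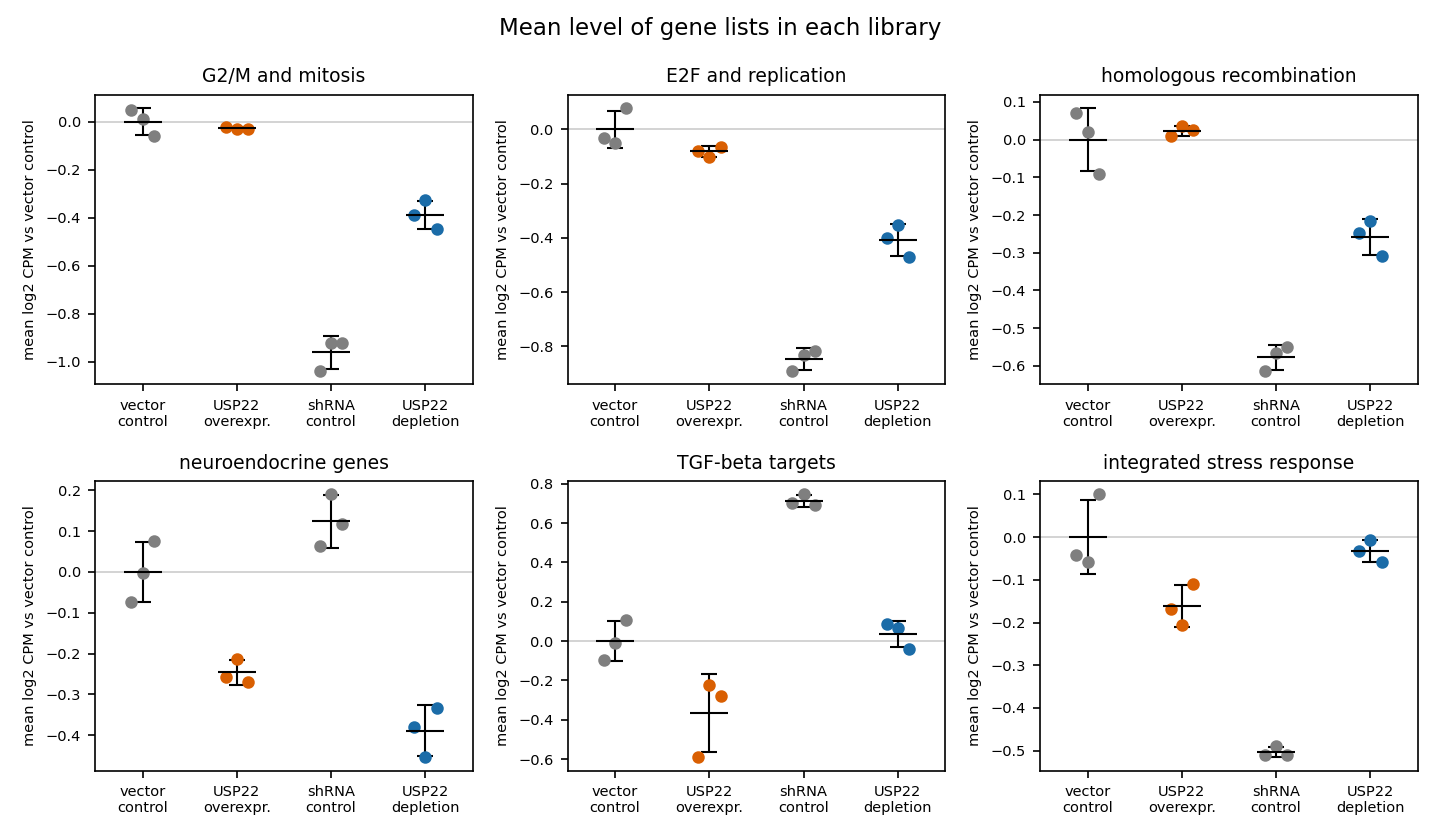
Mean log2 CPM of 6 gene lists in each library, relative to the mean of the vector control (vertical axes in log2 units, each panel on its own scale). Points are libraries, horizontal marks are group means and error bars are 1 SD (n = 3). The G2 and mitosis list averages -0.03 after overexpression, -0.96 in the shRNA control and -0.39 after depletion, and the TGF beta list -0.36, 0.71 and 0.04.

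Lists of DNA repair genes leaned upward on depletion by camera, but only homologous recombination held with an estimated correlation. Of 35 homologous recombination and Fanconi genes 20 rose and none fell (23 rose and 1 fell adjusted over the list alone), with a median of 0.35, camera adjusted p = 2.33e-11, and adjusted p = 0.031 with an estimated correlation. Mismatch repair (4 of 8 rose, 6 adjusted over the list alone), damage signalling (10 of 17, 11 adjusted over the list alone), nucleotide excision repair (8 rose and 2 fell of 27, 9 and 2 adjusted over the list alone) and base excision repair (4 of 20, also 4 adjusted over the list alone) had smaller medians of 0.22, 0.20, 0.16 and 0.12. Their camera calls (adjusted p = 0.00226, 0.000979, 0.00569 and 0.0438) were lost, with adjusted p = 0.16, 0.22, 0.32 and 0.63 with an estimated correlation. The base excision repair call also ended without depletion replicate 2 (adjusted p = 0.0913) and under the strict filter (adjusted p = 0.0809). End joining genes were not called (1 of 12 rose, 1 fell, also 1 and 1 adjusted over the list alone, camera adjusted p = 0.609). On overexpression the repair lists had camera adjusted p between 0.222 (end joining) and 0.983 (mismatch and nucleotide excision repair), and edgeR called falls in 2 of 35 homologous recombination, 2 of 12 end joining, 1 of 8 mismatch and 1 of 27 nucleotide excision repair genes. XPC, the damage recognition factor of nucleotide excision repair, was not called in either comparison. Its log2 fold change was -0.14 (SE 0.07, edgeR adjusted p = 0.316) on overexpression and 0.07 (SE 0.07, edgeR adjusted p = 0.592) on depletion, from 68.43 ± 7.72 CPM in the vector control and 56.5 ± 0.839 CPM in the shRNA control. Without vector control replicate 3 its overexpression value was -0.04 (edgeR adjusted p = 0.693).

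Amino acid stress genes also rose on depletion, while most TGF beta targets and some neuroendocrine genes fell. Of 27 integrated stress response genes 21 rose and 1 fell (21 and 2 adjusted over the list alone), including PSAT1 of serine synthesis (1.94-fold), asparagine synthetase ASNS (1.79-fold) and STC2 (1.8-fold), with camera adjusted p = 7.51e-20, and adjusted p = 0.031 with an estimated correlation. Of 12 TGF beta targets 8 fell and 1 rose (8 and 2 adjusted over the list alone), with a median of -0.86, camera adjusted p = 6.46e-14, and adjusted p = 0.012 with an estimated correlation: ID1 fell to 0.29, PMEPA1 to 0.513 and the inhibitory SMAD gene SMAD7 to 0.447 of control. Of 10 neuroendocrine genes 3 fell, also 3 adjusted over the list alone (camera adjusted p = 2.29e-08, and adjusted p = 0.011 with an estimated correlation). Without vector control replicate 3 the call with an estimated correlation was lost for the E2F list (adjusted p = 0.066). The control level matters here too: against the vector control the shRNA control lay lower in the integrated stress response list (median log2 difference -0.62) and higher in TGF beta targets (1.00), and the homologous recombination list was also lower (-0.67). By mean list level, the integrated stress response and TGF beta lists lay near the vector control after depletion (-0.03 and 0.04), against -0.50 and 0.71 in the shRNA control. A shift of the shRNA control alone would give such levels, and it cannot be told apart from an effect of USP22. The neuroendocrine list lay below both controls after depletion (-0.39, against 0.12 in the shRNA control).

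The remaining lists called on depletion did not keep their call with an estimated correlation. Ribosomal proteins (33 of 76 rose, 48 rose and 1 fell adjusted over the list alone), nuclear respiratory chain genes (14 of 50 rose and 1 fell, 21 and 1 adjusted over the list alone) and p53 targets (12 of 30 rose and 2 fell, 15 and 2 adjusted over the list alone) had medians of 0.18, 0.16 and 0.23. With an estimated correlation they had adjusted p = 0.48, 0.48 and 0.31. Immediate early genes (10 of 20 fell and 1 rose, 11 and 1 adjusted over the list alone) and interferon-stimulated genes (10 of 37 fell and 3 rose, 13 and 3 adjusted over the list alone) had medians of -0.47 and -0.22, with adjusted p = 0.089 and 0.37 with an estimated correlation. The interferon call also ended without depletion replicate 3 (camera adjusted p = 0.0898). Among markers of cells outside the line, fibroblast markers (3 of 9 fell, 1 rose, also 3 and 1 adjusted over the list alone, median -0.31) and markers of other adherent epithelial lines (5 of 14 fell, 1 rose, 6 and 2 adjusted over the list alone, median -0.37) were lower on depletion by camera, with adjusted p = 0.16 and 0.066 with an estimated correlation. Without vector control replicate 3 the fibroblast markers had adjusted p = 0.032 with an estimated correlation. ACTA2 is one of the fibroblast markers. Leukocyte and endothelial markers were not called (camera adjusted p = 0.386). Ribosomal and p53 lists were lower in the shRNA control than in the vector control (-0.70 and -0.58) and interferon genes higher (0.84), so these shifts also have to be read with the control level.

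The members of the USP22 module and related factors mostly did not pass the test. The list of 6 further genes of the deubiquitinase module and related deubiquitinases was not called by camera (adjusted p = 0.716 on overexpression and 0.755 on depletion). By edgeR 0 of its genes passed in either comparison, also 0 adjusted over the list alone, against 1 and 2 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 0 and 0 by limma voom. The adaptor ATXN7L3 had log2 fold changes of -0.10 on overexpression and -0.10 on depletion (edgeR adjusted p = 0.586 and 0.521), ENY2 had 0.02 and 0.18 (0.881 and 0.0593), and the related protease USP51 had -0.41 and -0.37 (0.157 and 0.101) at about 2.086 CPM in the vector control. The SAGA acetyltransferase KAT2A had -0.01 and 0.05 and the pioneer factor FOXA1 0.03 and 0.08 (edgeR adjusted p = 0.959, 0.734, 0.849 and 0.434). On overexpression MYC had a log2 fold change of -0.06, CCND1 of -0.04, CDKN1A of 0.10 and E2F1 of -0.37 (edgeR adjusted p = 0.678, 0.705, 0.532 and 0.0544). E2F1 passed the threshold without vector control replicate 1, 2 or 3, with log2 fold changes of -0.42, -0.47 and -0.20 (edgeR adjusted p = 0.04, 0.0109 and 0.0339), and CDKN1A without replicate 3 at 0.22 (edgeR adjusted p = 0.00727). ENY2 passed on depletion without vector control replicate 3, shRNA control replicate 2 or depletion replicate 3 (log2 fold change 0.18, 0.24 and 0.25, edgeR adjusted p = 0.00473, 0.0455 and 0.0242). It also passed under RLE scaling (0.0496), the strict filter (0.025), DESeq2 (0.0275), only the 6 libraries compared (0.00743), quality weights (0.00184) and protein-coding genes alone (0.019). E2F1 on overexpression also passed with no filter on low counts (0.000308), DESeq2 (0.0144), quality weights (0.02) and protein-coding genes alone (0.0474). With quality weights CDKN1A passed on overexpression (log2 fold change 0.21, adjusted p = 0.00348) and USP51 on depletion (-0.39, adjusted p = 0.0207).

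The 2 experiments were then set side by side. If raising and lowering USP22 had opposite effects, genes called in both would move in opposite directions. PCDH11Y, a protocadherin with a near-identical copy on another chromosome, rose on overexpression and fell on depletion (log2 fold changes 1.05 and -2.02), as did LPAR3, a lysophosphatidic acid receptor (0.48 and -1.74), DTNA (0.49 and -1.34) and NLGN2, a synaptic adhesion protein (0.51 and -0.54). The NLGN2 rise was lost without vector control replicate 1 or any 1 overexpression replicate (edgeR adjusted p = 0.0601 to 0.103) and with only the 6 libraries compared (0.0642). PRUNE2 (-0.54 and 0.54), HPGD, a prostaglandin dehydrogenase (-0.72 and 0.75), LPAL2 (-0.87 and 0.80), SLC43A1, an amino acid transporter (-0.73 and 0.54), and EPB41L2 (-0.59 and 0.58) did the reverse. The HPGD fall did not pass with only the 6 libraries compared (log2 fold change -0.70, edgeR adjusted p = 0.0582). In each of these genes of opposite direction the shRNA control already differed from the vector control (edgeR adjusted p under 0.05), opposite to the change on depletion. The log2 differences were 1.93 for PCDH11Y, 0.49 for LPAR3, 0.34 for DTNA and 1.35 for NLGN2. They were -1.42 for PRUNE2, -0.47 for HPGD, -2.78 for LPAL2, -1.75 for SLC43A1 and -0.81 for EPB41L2. The depletion changes of these genes have to be read with the control level. More genes moved the same way in both. RALYL (1.84 and 1.57) and KCNJ3 (2.29 and 1.13) rose in both, and CLU (-2.47 and -2.18), ACTA2 (-1.58 and -2.84) and the desmosomal cadherin DSC3 (-1.57 and -1.79) fell in both.

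Of the 593 genes called in both comparisons, 470 moved in the same direction (125 rose and 345 fell) and 123 in opposite directions. Independent lists would share 36.9 risers, 70.9 fallers and 105 genes of opposite direction. With all libraries the opposite sets did not clearly exceed this: 52 genes rose on overexpression and fell on depletion against 41 for independent lists (Fisher's exact test across genes, p = 0.08), and 71 did the reverse against 63.8 (p = 0.35). The comparisons share no library, but the spread of each gene was estimated from all libraries together. Across all 26076 genes, which are not independent replicates, the fold changes had a Pearson r of 0.142 and a Spearman rho of 0.0875. The counts without vector control replicate 3 were 813 in the same and 400 in opposite directions, against 303 and 300 for independent lists. Genes of opposite direction thus exceeded the number for independent lists in that fit, though this excess was not tested. Numbers for independent lists take every tested gene as equally likely to be called, so an excess alone does not show opposite effects of USP22. Same and opposite counts were 285 and 56, 275 and 50, and 312 and 74 without overexpression replicate 1, 2 and 3, and opposite genes numbered 70, 72 and 71 without shRNA control replicate 1 or 2 or depletion replicate 1. The counts were 201 and 36 with each experiment fitted on its own 6 libraries.

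**Figure D3:**
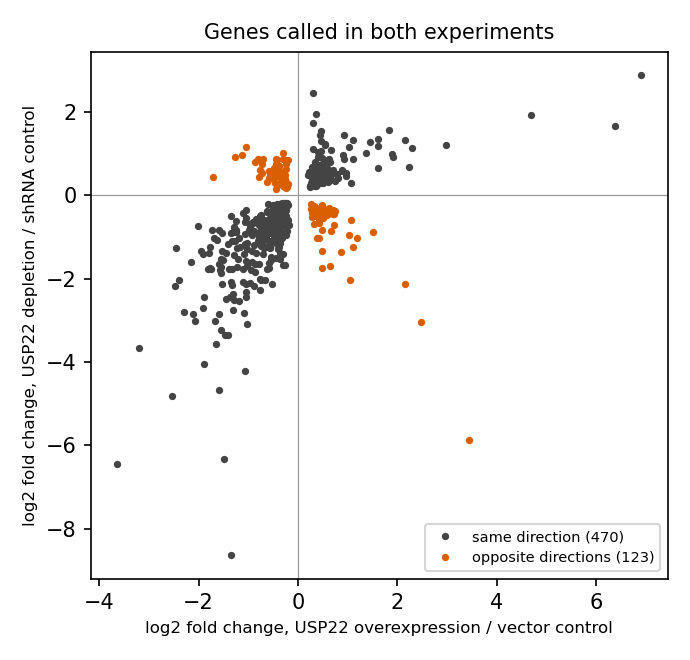
Log2 fold change on USP22 overexpression (horizontal axis) against log2 fold change on USP22 depletion (vertical axis) for the 593 genes called in both comparisons. Each point is a gene. The 470 genes of the same direction lie at the lower left and upper right and the 123 of opposite directions at the upper left and lower right.

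In one model of both experiments, 2840 genes had a joint effect of higher USP22, the average of the overexpression effect and the sign-reversed depletion effect (1280 higher, 1560 lower, edgeR). G2 and mitosis genes were lower with higher USP22 in 47 of 52 cases (49 adjusted over the list alone, median -0.31, adjusted p = 0.031 with an estimated correlation) and integrated stress response genes in 21 of 27 (22 fell and 1 rose adjusted over the list alone, median -0.33, adjusted p = 0.031 with an estimated correlation). E2F and replication genes were lower in 43 of 52 (47 adjusted over the list alone, median -0.25, adjusted p = 0.047 with an estimated correlation). The E2F call was lost without vector control replicate 3 (adjusted p = 0.073 with an estimated correlation). On overexpression alone the G2 and mitosis list had a median of -0.02 (camera adjusted p = 0.397), with 0 of 52 genes called by edgeR, 13 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom. Its median there was -0.06 without vector control replicate 3, and 4 of 52 genes fell (camera adjusted p = 0.0331, and adjusted p = 0.96 with an estimated correlation). In a test of the difference between the experiments, 4017 genes differed (1701 above 0 and 2316 below). More genes lay above 0 with no filter on low counts (2547 and 2265), with the strict filter (2132 and 2076), without shRNA control replicate 2 (1659 and 1639) or depletion replicate 3 (1826 and 1681), and in a fit of protein-coding genes alone, chosen after seeing the data (2114 and 1902). The joint count was 5381 without vector control replicate 3.

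The 2 control lines differed in more genes than either manipulation changed. The shRNA control was lower than the vector control in all 76 ribosomal protein genes (median log2 difference -0.70), in 52 of 52 G2 and mitosis genes (-0.97), in 51 of 52 E2F genes (-0.82) and in 52 of 53 MYC targets (-0.80). It was higher in 26 of 37 interferon-stimulated genes (0.84, 2 lower) and 9 of 12 TGF beta targets (1.00, 2 lower). With an estimated correlation the G2 and mitosis, E2F and MYC lists held (adjusted p = 0.03, 0.03 and 0.033), and the ribosomal, interferon and TGF beta lists had adjusted p = 0.094, 0.061 and 0.094. The former 3 calls were lost without vector control replicate 3 (adjusted p = 0.074 each). Adjusted over each list alone, 76 ribosomal, 52 G2 and mitosis, 52 E2F and 52 MYC genes were lower, and 27 interferon and 9 TGF beta genes were higher. In all, 11211 genes differed, 5665 higher and 5546 lower in the shRNA control (edgeR). These lines differ in vector and in doxycycline treatment, which cannot be told apart.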

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

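The tests of vector control replicate 3 as a cause of the shared calls, and of the level of the shRNA control as a cause of the cell cycle changes, were chosen only after the results were seen. For each named gene and list the effect of higher USP22 was compared between the experiments: the overexpression effect minus the sign-reversed depletion effect, on the log2 scale. A value near 0 comes from equal and opposite responses or from no response, and other values from the same direction in both, a change in one, or opposite changes of unequal size, as for PCDH11Y, LPAR3, DTNA and USP22. Of 74 named genes 57 had a difference that passed the test of the difference itself (edgeR adjusted p under 0.05), 29 above 0 and 28 below. Apart from the preset genes, the named genes were chosen by their change in these same comparisons, so the choice shapes this count. Over all tested genes 4017 of 26076 passed (15.4%). Among large rises of either comparison the differences were KCNJ3 3.42, RALYL 3.4, UGT2B11 2.74, SLC22A3 2.72, UGT2B10 2.31, UGT2B15 2.04, FUCA2 1.95, UGT2B28 1.69 and UNC13C 1.35. Among large falls they were DAPK1 -5.08, CLU -4.65, ACTA2 -4.42, ZNF608 -3.80, GBP2 -3.79, GBP1 -3.49, AGR2 -3.37, DSC3 -3.35, MDGA1 -2.68, TMEM45B -2.57, THBS1 -1.97, H2AJ -1.74 and H4C16 -1.25. Cell cycle, histone and MYC-related genes had H2BC18 1.35, H3C13 1.19, BUB1 0.78, PRIM1 0.75, PTTG1 0.74, CENPF 0.71, PCNA 0.65, GINS4 0.64, MYC 0.62, POLR1B 0.49, H1-2 0.49, PAICS 0.35 and HSPD1 0.32. Amino acid stress genes had PSAT1 0.92, ASNS 0.64, STC2 0.59 and SLC3A2 -0.39. Mitochondrial genes had MT-ND4L 0.88, MT-ND5 0.64 and MT-CYB 0.64. Neuroendocrine genes, KLK3 and PMEPA1 had DDC -3.4, SYT4 -3.06, KLK3 -2.64, ENO2 -1.25 and PMEPA1 -1.19. TGF beta list genes had ID1 -2.74, ID3 -1.80, SMAD7 -1.57 and ID2 -1.43. The remaining genes were LPAR3 -1.26, PCDH11Y -0.97, DTNA -0.85, USP51 -0.78, CDKN1A -0.72 and USP22 0.63.

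By camera 15 of the reported lists had a difference. With an estimated correlation the neuroendocrine and TGF beta lists alone held (adjusted p = 0.0027 and 0.008), and the others lost their call (adjusted p = 0.069 to 0.81). The median values of the 15 lists were 0.64 for the mitochondrial genome, 0.59 for replication-dependent histones, 0.52 for G2 and mitosis, 0.38 for E2F and replication, 0.32 for homologous recombination, 0.31 for the integrated stress response, 0.19 for p53 targets, 0.18 for MYC targets, 0.15 for mismatch repair and 0.0795 for ribosomal proteins. They were -1.24 for TGF beta targets, -0.61 for immediate early genes, -0.26 for neuroendocrine genes, -0.19 for fibroblast markers and -0.15 for markers of other epithelial lines. The fibroblast median was 0.04 without vector control replicate 3, although the test still pointed down, and the list of other epithelial lines lost its call (camera adjusted p = 0.0852).

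More genes called in both experiments moved in the same direction than in opposite directions, 470 against 123. GC content and gene length are argued against as the whole cause, since a correction by bins of both, which changed the sign of 12% of all genes on overexpression and 5.19% on depletion, moved these genes by a median of 0.05 and 0.04 against median fold changes of 0.50 and 0.63 (log2), with 79% of the same sign before and after. The ratio was 3.61 under upper-quartile scaling and 3.82 under TMM. These scalings were nearly alike, with median log2 fold changes of all genes of 0.0189 and -0.00845 on overexpression. On depletion these medians were -0.0166 and 0.000238, so this test cannot decide on library scaling. Vector control replicate 3 is argued against only as the whole cause. The ratio over that of independent lists was 2.02 without it and 3.72 with it, so it may carry part of the excess. Over 60 splits within the experiments the highest other gave 0 genes in either direction, but other splits call almost no genes in a single experiment (at most 0 on overexpression and 5 on depletion), so this says nothing about the overlap. What also stays open is that a response to a change of USP22 in either direction, or to carrying a construct against its own control, may give such genes, and the design has no second construct to separate these.

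Cell cycle genes were higher on depletion than in the shRNA control. Scaling as the cause is argued against, since a library factor moves all genes alike and the G2 and mitosis median lay 0.606 above that of all genes. The depletion libraries lay between the controls, with a mean list level of -0.388 against the vector control, where the shRNA control had -0.963. A low growth state of the shRNA control culture may therefore account for part of the difference, but it cannot be told apart from an effect of USP22, because each shRNA has a single line and there is no untreated parent. The labels name a single hairpin against USP22, so effects on other targets stay open and untested.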

How the results depend on the processing

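Voom with sample quality weights, the fit of protein-coding genes and the depletion comparison without vector control replicate 3 were chosen after seeing the data. USP22 kept its direction and passed under every alternative run, with 1.47 to 1.59 on overexpression and -0.893 to -0.848 on depletion over the fits without 1 replicate. RLE scaling, limma voom and leaving out the 20 most abundant genes kept each count within 1.5 times. The count of overexpression genes was 2062 with no filter on low counts, 1781 by DESeq2 and 327 with only the 6 libraries compared, and the depletion count was 8115 with only its 6 libraries. Genes of opposite direction numbered 255 with no filter and 225 by DESeq2, and with 6 libraries per fit 201 genes moved the same way and 36 in opposite ways. The correlation of fold changes across genes was 0.00985 with no filter, 0.272 with the strict filter, 0.193 with 6 libraries per fit and 0.208 with protein-coding genes. The strict filter left 6 overexpression lists, and an estimated correlation left 1 and 7 lists. The joint effect and the difference have no value with 6 libraries per fit. Stricter thresholds gave, for overexpression, depletion, joint effect and difference, 206, 825, 139 and 1114 genes at 2-fold or more and 469, 3053, 1359 and 2135 at an adjusted p under 0.01, which fewer passing genes explain by construction. Quality weights gave 2342, 9613, 6327 and 6913 genes, with 985 of same and 521 of opposite direction. For the other changes the cause was not tested.

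With the replicate number as a block the counts were 1098, 5272, 2959 and 4208, with 11308 between the control lines, 10 and 22 lists, 476 genes of same and 137 of opposite direction and r = 0.144. Whether the numbers pair the libraries stays undecided. Deviations of like-numbered libraries had weak correlations of -0.022 to 0.083, with the own number the best match for 2 of 3 in each experiment. Over the fits without 1 replicate the counts ranged from 511 to 1876 on overexpression, 3535 to 8375 on depletion, 1928 to 5381 for the joint effect, 2933 to 5955 for the difference, 9519 to 12335 between the control lines, 275 to 813 for same and 50 to 400 for opposite directions, with r from 0.111 to 0.162 and 9 to 11 and 19 to 23 lists. The depletion count rose without vector control replicate 3 because that library enters it through the shared spread. Genes that changed sign had not passed the test. Over the fits without 1 replicate the overexpression values ran from -0.0946 to 0.0106 for MYC, -0.182 to 0.0418 for ATXN7L3, -0.0121 to 0.0601 for ENY2, -0.0904 to 0.12 for KAT2A and -0.0342 to 0.0631 for FOXA1, and the depletion values of CCND1 from -0.0404 to 0.00012. On overexpression KAT2A had 0.00733 with no filter, 0.0173 with the strict filter, 0.00534 with 6 libraries, 0.106 with quality weights and 0.0246 with protein-coding genes. Quality weights gave 0.000982 for MYC, 0.0248 for ATXN7L3, -0.00597 for ENY2 and -0.028 for FOXA1. Of named genes under alternatives 1573 values kept direction and side of the threshold, 19 newly passed, 27 no longer passed and 16 changed sign. For lists these were 288 kept and 37 no longer passed. Of simulated 1.5-fold changes 41.2% were recovered on overexpression; depth was not varied, and replicates differed by more than counting noise, so what depth limits was not tested.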

Other observations

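The test of activation of the HOXC region was chosen only after the result was seen. Beyond the lists described for the control lines, the shRNA control was lower than the vector control in 25 of 35 homologous recombination genes (1 higher; 26 lower and 1 higher adjusted over the list alone) and in 25 of 30 p53 targets (2 higher; 25 and 3 adjusted over the list alone). Their medians were -0.67 and -0.58, and their camera calls held at adjusted p = 0.03 and 0.033 with an estimated correlation, but not without vector control replicate 3 (adjusted p = 0.074 and 0.12). Replication-dependent histones were lower in 23 of 24 cases (also 23 adjusted over the list alone, median -1.24, adjusted p = 0.16 with an estimated correlation) and integrated stress response genes in 22 of 27 (3 higher, also 22 and 3 adjusted over the list alone, median -0.62, adjusted p = 0.094 with an estimated correlation). MYC differed by -1.64, SLC22A3 by -4.27 and MDGA1 by 3.52 on the log2 scale (edgeR adjusted p = 3.34e-11, 1.24e-12 and 2.29e-12). The latter pair were singled out after their values were seen.

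Several lists had no camera call on depletion although members passed. Of 18 fatty acid synthesis genes 7 rose and 4 fell on depletion (8 and 4 adjusted over the list alone, camera adjusted p = 0.143), and of 24 cholesterol synthesis genes 5 rose and 1 fell (also 5 and 1 adjusted over the list alone, camera adjusted p = 0.71). Of 12 luminal prostate genes 6 fell and 2 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.0519), and of 21 unfolded protein response genes 6 fell (8 adjusted over the list alone, camera adjusted p = 0.0635). The luminal, unfolded protein response and mitochondrial genome lists were called on depletion without vector control replicate 3 (camera adjusted p = 0.0332, 0.0239 and 0.00934), the latter from 0.0607 with all libraries, and all 3 calls were lost with an estimated correlation (adjusted p = 0.57, 0.61 and 0.58). On overexpression the interferon and cholesterol synthesis lists were then called upward (camera adjusted p = 0.00709 and 0.0332, from 0.0558 and 0.45), and these were lost as well (adjusted p = 0.81 and 0.93 with an estimated correlation).

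Vector control replicate 3 stood apart from replicates 1 and 2, with a quality weight of 0.121 where the other libraries had 0.634 to 2.73. Counting noise is argued against: among genes with a mean of at least 1000 reads its deviation was 3.61 times the SD expected from the other replicates. A library of another group under its label is argued against as well, since its deviation ran at most 0.37 of the way to another group (overexpression), though a sample from outside the series stays open. Bins of GC content and gene length removed 47.9% of its excess variance, between the bounds set for and against, so a technical difference of this kind may be part of it and cannot be told apart from others. No biological explanation was tested.

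MIR196A2, chosen after its values were seen, had 0 reads in all vector control and overexpression libraries, and 49723 reads summed over the shRNA control and 43206 over the depletion libraries. A hypothesis is that these reads from the shRNA construct were assigned to this gene: a construct would give at most a few such genes, and exactly 1 gene had 0 reads in all vector control and overexpression libraries and at least 1000 in every shRNA library. Any cause that acts on this gene alone would give the same count. The sequence of the construct was not used here, so the source of the reads stays open. Activation of the HOXC region, which holds the gene, is argued against by a median log2 difference of 0.346 between the control lines over 9 HOXC genes, although HOXC4 differed by 1.52 and HOXC5 by 1.03 (edgeR adjusted p = 2.72e-05 and 0.0181).

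Other splits of the libraries were fitted in the same way. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 1072 genes on overexpression, 5172 on depletion and 11211 between the control lines, and the highest other split 0, 5 and 0. For lists the real values were 10 and 20 and the highest others 10 and 17, so another split of the overexpression libraries gave as many lists as the real one (2 of 10 splits). Over 60 drawn splits within both experiments the real one was the highest for the joint effect (2840 genes, highest other 1939) and the difference (4017, highest other 2564). This argues against chance only for the case that neither experiment has an effect. Other splits could keep the real grouping of a single experiment, and the depletion effect enters both counts. The splits therefore do not show that overexpression adds to either count. For the correlation across genes (0.142, highest other 0.135) the gap is smaller than its jackknife SD of 0.042, and r was 0.00985 with no filter on low counts, so chance is not excluded.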
